A study of Cymbopogon flexuosus and Cymbopogon winterianus with 4 samples.

How the data were processed

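RNA sequencing counts were analysed from leaves of 2 aromatic grasses, Cymbopogon flexuosus (lemongrass) and Cymbopogon winterianus (citronella), with 2 libraries per species from field-grown plants kept without treatment. Groups were taken from the sample titles. The labels do not say whether the 2 libraries of a species came from separate plants, so p-values measure the spread between these libraries, which may be technical.

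The authors deposited 2 count tables of whole-number counts per contig feature, and each holds a column for each of the 4 libraries per the file headers. One table has feature IDs with the prefix used for the lemongrass libraries (here "lemongrass contigs"), and the other has the prefix used for the citronella libraries ("citronella contigs"). Total RNA was made into libraries with an Illumina TruSeq RNA kit and read as paired ends, per the labels' protocols. The submitters' processing notes name FastQC 0.11.2, Trimmomatic 0.32, HISAT2, SAMtools, HTSeq and edgeR, with no role or order. The column totals differ, so the tables were taken as raw counts. In the first citronella column on citronella contigs the counts of abundant contigs are compressed, with a highest count of 5782 against 33170 in the second, and whether its reads were normalized or subsampled before counting is not given in the sources used here. The levels and folds that use this column carry that doubt. The origin of the contigs, the reference and the treatment of reads that fit more than 1 contig are not given in the sources used here. Reads from near-identical contigs could therefore be split or lost, and the counts of any single contig are uncertain to that extent. Contig lengths were not used here. The species were compared contig by contig, but ranks by CPM, abundance classes and shares of leading contigs are not corrected for contig length.

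The files do not pair contigs with gene names, descriptions or coordinates. The 15 lists of pathway and tissue marker genes fixed before the data were examined could therefore not be tested, and contigs are reported by ID. IDs of the 2 sets do not overlap, so no contig of one set was matched to one of the other. Both columns of each species were used in each table, and no row lacked a contig ID.

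Levels are given as CPM, the deposited counts as a share of their column total on the usual CPM scale. Totals ran from 4875674 to 9485822 counts on lemongrass contigs and from 5132053 to 6369924 on citronella contigs. A count of 0 allows a level of up to 3 counts, which is 0.316 to 0.615 CPM per library. Floors and the exact intervals of folds cover counting error only. The other intervals treat contigs as independent, which they are not, and hold no spread between libraries.

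The species were compared within each table with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the species as group, TMM scaling, glmQLFit and glmQLFTest, 2 libraries against 2). P-values were two-sided and adjusted by Benjamini-Hochberg over all contigs tested in that table, and an adjusted p below 0.05 was called. Fold changes are citronella minus lemongrass on the log2 scale, and their standard errors are the fold change divided by the square root of F. Where all libraries of a species had 0 counts, the fold was computed against a floor of 3 counts over the group and given as a lower bound. The named contigs followed a rule fixed together with the gene lists: for contigs without names, the 2 with the largest absolute log2 fold change in each direction among called contigs whose libraries did not overlap between species and whose mean was at least 5 CPM in the higher species. This order used edgeR's log2 fold change without the floor of 3 counts. Contigs with 0 counts in a species could thus rank higher than by their lower bound. The 2 most abundant contigs of each species were also named. Counts of contigs near-absent from 1 species (10 or more counts in both libraries of the other, at most 3 in it together) and the classes by abundance and fold were chosen after seeing the data.

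Replicates were compared on log2(CPM + 1) over contigs with a mean count of at least 10, by Pearson's r and Spearman's rho across contigs, the number of contigs over 2-fold apart, edgeR's common dispersion and a chi-square statistic against sampling noise. Contigs are not independent replicates. The chi-square comparison used deposited counts and column totals.

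The fit was tested on simulated data with 200 changed contigs per table, drawn with the real means, library sizes and dispersion. Of the 100 contigs changed 2-fold, edgeR recovered 37% among 25107 lemongrass contigs and 30% among 34705 citronella contigs. Of the 100 changed 4-fold, it recovered 92% and 66%. False calls numbered 7 and 1. All libraries of a table were drawn with the same dispersion trend, and far fewer contigs changed than were called in the data. The recovered shares therefore do not measure the power of the comparison itself.

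The comparison was repeated with RLE, upper-quartile or no scaling factors, other count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), a test against a 2-fold change, the replicate number as a block, removal of the 10 most abundant contigs, and each library left out in turn. For the profile and the replicate comparison, other detection minimums, thinning to the smallest library, other pseudocounts and TMM-scaled CPM were used. Where a species was left with 1 library, that library was assumed to vary like those of the other species. The common dispersion was 0.015 on lemongrass and 0.035 on citronella contigs in the main fit. Without either lemongrass library it was 0.024 and 0.059, and without either citronella library 0.004 on both sets. Numbers called with a library left out therefore also depend on which pair set the spread. Cyclic loess offsets (pseudocount of 0.5 counts) and a mean count of 50 or more were added after seeing the data.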

Results

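Leaf transcripts of lemongrass (Cymbopogon flexuosus) and citronella (Cymbopogon winterianus) were counted in 2 libraries per species. Both are grasses grown for their scented leaf oils, and the series concerns the evolution of scent in the genus. Each library was counted on 25576 lemongrass contigs and on 42250 citronella contigs, so the 2 species were compared on the same features within each set. The 2 comparisons used the same 4 libraries and are not independent of each other.

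The lemongrass libraries gave 5787640 and 6636226 counts on lemongrass contigs, and 5540867 and 6369924 on citronella contigs. Their totals were thus 4.45% and 4.18% higher on contigs of their own species. The second citronella library gave 4875674 counts on lemongrass contigs and 5132053 on its own, a gain of 5.26%. The first citronella library differed from the other 3. It gave 9485822 counts on lemongrass contigs but 6222870 on citronella contigs, so its total fell by 34.4% on contigs of its own species.

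The first comparison describes what each species' leaves expressed. On lemongrass contigs, 24814 ± 458 contigs (SD, n = 2) had 10 or more counts in lemongrass and 23157.5 ± 1272 in citronella. On citronella contigs the numbers were 24183 ± 851 in lemongrass and 35695.5 ± 5568 in citronella. The citronella mean combined 39633 contigs in the first library with 31758 in the second, at totals of 6222870 and 5132053 counts. Thinned to the smaller total, the mean was 34706.5. This was still above the second library, so depth did not account for the whole gap. The 100 most abundant lemongrass contigs took 13.1% ± 0.0702 of the counts in lemongrass and 13.9% ± 1.17 in citronella (SD, n = 2), a difference smaller than the spread between the citronella libraries. On citronella contigs they took 13.3% ± 0.0591 in lemongrass. In citronella they took 5.03% in the first library and 12.1% in the second.

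Levels of the leading contigs were ranked by the mean over the 2 libraries of a species. On lemongrass contigs g.contigcf1893 ranked first in both species, at 4838 ± 112 CPM in lemongrass and 5572 ± 265 CPM in citronella (SD, n = 2). The second was g.contigcf1897 in lemongrass, at 3143 ± 66.2 CPM against 3035 ± 64.4 CPM in citronella. In citronella the second was g.contigcf1900, at 3389 ± 160 CPM against 2674 ± 48.4 CPM in lemongrass. On citronella contigs, g.contigcw4247 and g.contigcw4243 had the highest means in both species, but in citronella this rank came from the second library. In lemongrass they stood at 6738 ± 26.5 and 3894 ± 38.2 CPM. In citronella, g.contigcw4247 stood at 765 CPM in the first library and 6463 CPM in the second, and g.contigcw4243 at 271 and 3661 CPM. The first citronella library was thus far below the other 3 for these contigs, and neither led there, since its highest contig stood at 929 CPM. It was close to the second library for the leading lemongrass contigs.

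The spread between libraries of 1 species was smaller in lemongrass than in citronella. The lemongrass libraries correlated across contigs with r = 0.983 and rho = 0.968 on lemongrass contigs, and r = 0.981 and rho = 0.964 on citronella contigs. The citronella libraries gave r = 0.975 and rho = 0.966 on lemongrass contigs, and r = 0.956 and rho = 0.910 on their own. On lemongrass contigs, 326 of 24938 contigs were over 2-fold apart between the lemongrass libraries and 557 of 23520 between the citronella libraries. On citronella contigs the numbers were 501 of 24001 and 3824 of 36548. The 3824 became 2066 with TMM-scaled CPM, 864 at a mean count of 50 or more, 198 with a pseudocount of 10 CPM and 6419 with 0.1 CPM. Under each of these settings the citronella libraries had more such contigs than the lemongrass libraries on the same set. The biological coefficient of variation was 6.08% and 6.04% in lemongrass, and 15.1% and 21.6% in citronella, on lemongrass and citronella contigs respectively. Chi-square statistics per contig were 1.95 and 2.01 for lemongrass and 6.99 and 15.8 for citronella, where copies of 1 library would give no more than about 1. This checked only that no pair was 1 library deposited again.

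**Figure D1:**
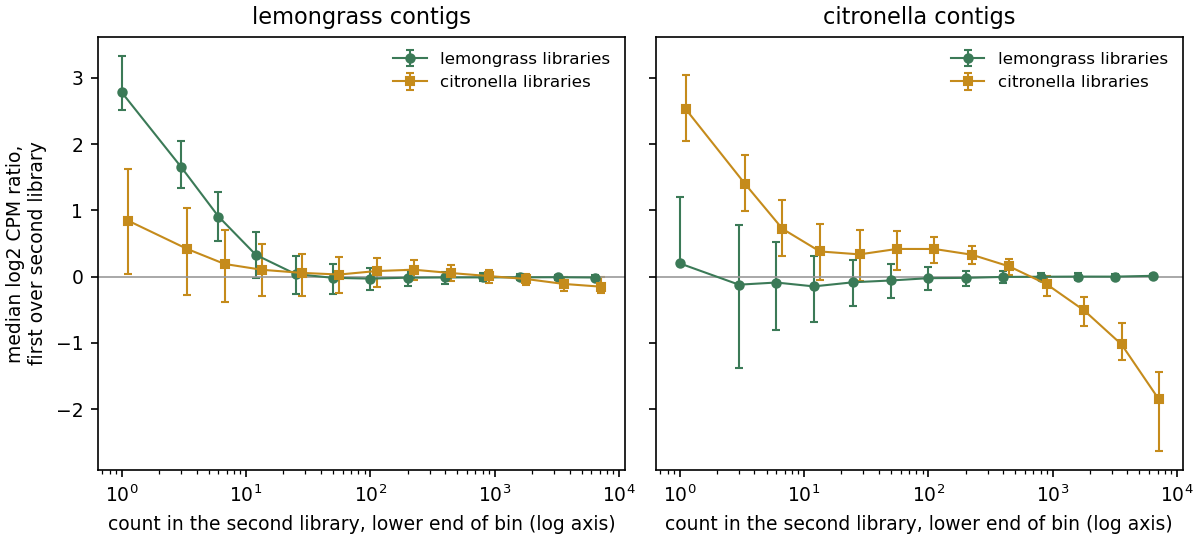
Median log2 CPM ratio of the first over the second library of a species (y axis), by the count in the second library (x axis, log scale), for lemongrass (green circles) and citronella (orange squares). Bars span the 25th to 75th percentiles of the contigs; the lower bar is left out for lemongrass in the lowest bin of citronella contigs, where it has no finite value. The citronella ratio on citronella contigs falls to -1.85 at 6400 or more counts but is -0.15 on lemongrass contigs.

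The gap between the citronella libraries depended on abundance and on the contig set. On citronella contigs with 6400 or more counts in the second library, the first library was lower by a median log2 CPM ratio of -1.85 (24 contigs). On lemongrass contigs of that abundance the median was -0.15 (36 contigs). At 100 to 200 counts in the second library, the first was higher by 0.42 on citronella contigs and by 0.09 on lemongrass contigs. The highest count of any citronella contig was 5782 in the first citronella library and 33170 in the second, and 37441 and 42804 in the lemongrass libraries. Whether the reads of the first citronella library were treated differently before they were counted on citronella contigs is not given in the sources used here. At the low end, 16 lemongrass contigs had under 5 counts in the first lemongrass library and 273 in the second, deeper one. On citronella contigs, 102 had under 5 counts in the first citronella library and 4386 in the second.

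The main comparison asked which leaf transcripts differed in level between the species. Of 25107 lemongrass contigs tested, 13754 (54.8%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The share was 39.8% with DESeq2, and 43.8% and 40.4% without the first and the second lemongrass library. The calls were split evenly, with 6817 higher in citronella and 6937 higher in lemongrass, and the median log2 fold change over all tested contigs was -0.005. This balance depends on the scaling and is no finding about the species. With upper-quartile scaling the split was 7473 to 6274 and the median 0.075. With library totals alone the split was 6506 to 6962 and the median -0.025. Without the first citronella library, 7002 were higher in citronella and 6712 in lemongrass. The libraries of the species did not overlap in CPM for 19448 contigs (77.5%), where chance gives 33.3%.

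On citronella contigs the calls leaned to citronella. Of 34705 contigs tested, 19809 (57.1%) passed, 11833 of them higher in citronella and 7976 higher in lemongrass by the same test. The share was 31.6% of 42245 contigs with DESeq2 and 39.4% with cyclic loess offsets. The median log2 fold change over all tested contigs was 0.24 in the main fit. This lean came from contigs of low abundance: the median was positive below rank 15000 by mean CPM and negative in each class above, from -1.08 in the leading 100 to -0.24 in the class ending at rank 15000. Over all contigs it was 0.14 without the first citronella library and 0.31 without the second. Without the first and the second lemongrass library it was 0.38 and 0.39. It was 0.05 with cyclic loess offsets and -0.01 at a mean count of 50 or more. Libraries did not overlap in CPM for 26180 contigs (75.4%). CPM takes library totals alone as scaling, which shifts this set as a whole, so no chance value is set beside this share. The split of calls became more even when the first or the second citronella library was left out. In these fits the lemongrass libraries alone set the spread. With library totals alone as scaling, the split was 14324 to 3544 and the median rose to 0.68, so the balance of directions on this set depended on the scaling.

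Large differences ran towards the species whose prefix the contigs carry. On lemongrass contigs, 2079 called contigs were at least 4-fold higher in lemongrass and 784 in citronella. At 16-fold or more the numbers were 448 and 8. On citronella contigs, 7472 were at least 4-fold higher in citronella and 1092 in lemongrass, and at 16-fold or more the numbers were 2489 and 48. The direction of this lean did not change when each library was left out, although its size did. Without the first lemongrass library, 2084 lemongrass contigs were at least 4-fold higher in lemongrass and 1217 in citronella. Without the first citronella library, 1231 lemongrass contigs were at least 4-fold higher in citronella, and on citronella contigs the numbers became 5993 higher in citronella and 1722 in lemongrass. At 16-fold or more, the lemongrass contigs higher in citronella became more numerous without the first library of either species. They became fewer without the second lemongrass library and changed little in number without the second citronella library. The 48 citronella contigs higher in lemongrass became more numerous without the first citronella library, and the 2489 higher in citronella became fewer without either lemongrass library. Of the 2489, 542 had 0 counts in lemongrass, so their folds were lower bounds. Such a bound falls when the total of the lemongrass group falls, as it does when a lemongrass library is left out. How much of the change came from this was not tested. At 4-fold or more, the number higher in citronella rose without the first lemongrass library and fell slightly without the second.

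**Figure D2:**
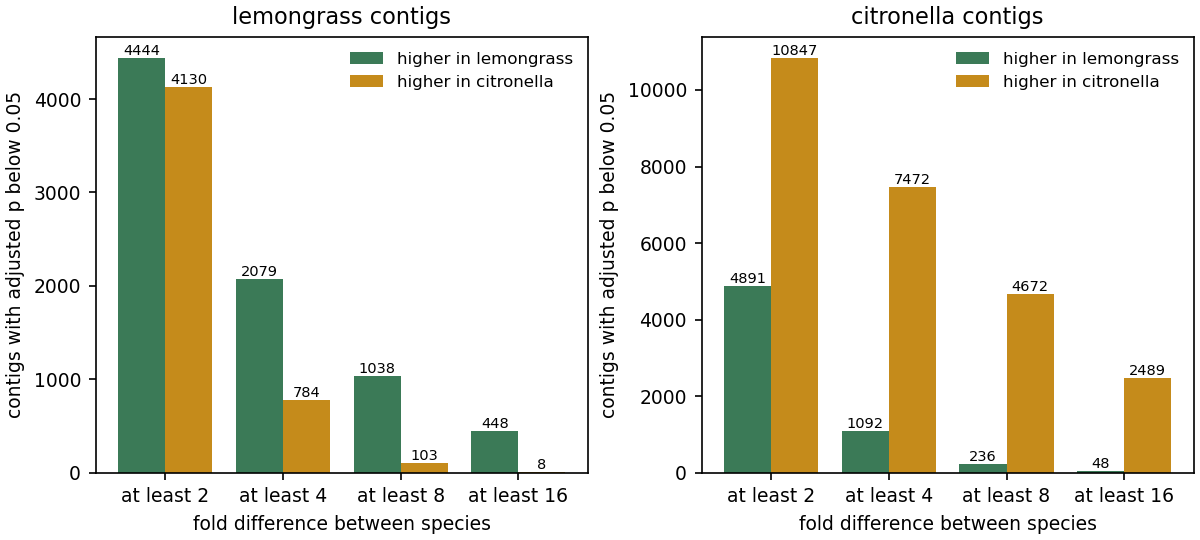
Number of contigs with an adjusted p below 0.05 (y axis) at or above each fold difference (x axis), on lemongrass contigs (left) and citronella contigs (right, with its own y scale). Green bars are contigs higher in lemongrass and orange bars contigs higher in citronella. At 16-fold or more, 448 lemongrass contigs are higher in lemongrass against 8, and 2489 citronella contigs are higher in citronella against 48.

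Some contigs were near-absent from the other species. On lemongrass contigs, 183 had 10 or more counts in both lemongrass libraries and at most 3 counts in the citronella libraries together. The opposite was seen in 0 lemongrass contigs, but 13 of 25576 had 3 or fewer counts in the first lemongrass library, which left little room for it. These 183 contigs took 0.116% and 0.113% of the counts of the lemongrass libraries, with a median level of 4.29 CPM. On citronella contigs, 3348 were detected in both citronella libraries and near-absent from lemongrass, and 0 showed the opposite, where again 69 of 42250 had 3 or fewer counts in the first citronella library. The 3348 contigs took 2.52% and 2.07% of the counts of the citronella libraries, at a median of 3.93 CPM, and 1252 of them had 0 counts in both lemongrass libraries. With the first library of the species named by the contig prefix left out, the numbers were 193 and 3467. The opposite was then seen in 73 lemongrass and 363 citronella contigs, with at most 3 counts asked of 1 library alone. At this depth 0 counts allow a level of up to 3 counts, and 1 to 3 counts allow a higher one.

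On lemongrass contigs, abundant contigs differed by smaller folds than rare ones, although a larger share of them was called. On both sets the folds by class are over all contigs tested, called or not. Counting noise enlarges absolute folds at low counts, and its part in the differences between classes was not tested. Among the 100 most abundant lemongrass contigs, the median absolute log2 fold change was 0.33, and 34 were called higher in citronella and 28 in lemongrass. Among lemongrass contigs ranked below 15000, the median absolute value was 0.86, 14.9% were over 4-fold apart against 2% of the leading 100, and 45.6% were called against 62%. The median log2 fold change of the leading 100 lemongrass contigs was 0.05. It was 0.16 without the first citronella library, and 0.01 and 0.10 without the first and the second lemongrass library. Without the second citronella library its sign turned, at -0.02.

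On citronella contigs the order of folds differed, with a median absolute log2 fold change of 1.09 in the leading 100 and of 0.69, 0.59 and 0.86 in the 3 classes from there down to rank 15000. It was highest below rank 15000, at 1.34, where 33.5% were over 4-fold apart against 2% of the leading 100 (11% with limma-voom). This order turned without the second citronella library, where the leading 100 had a median of 2.15 with 61% over 4-fold apart, against 1.19 and 29.2% below rank 15000. Numbers called with 1 library left out are not compared in these classes, since the spread then came from the libraries of the other species alone. Among the 100 most abundant citronella contigs, 20 were called higher in lemongrass and 0 higher in citronella by edgeR, with a median log2 fold change of -1.08. At an unadjusted p under 0.05 the numbers were 26 and 0. DESeq2 called 34 and 1, and limma-voom 30 and 1. The median log2 fold change of these 100 contigs was -0.44 without the first citronella library and -2.15 without the second. It was -1.13 and -1.11 without the first and the second lemongrass library. Of citronella contigs ranked below 15000, 8458 were called higher in citronella and 1704 higher in lemongrass. The median log2 fold change below rank 15000 stayed positive with each library left out, over the contigs of that class tested in each fit. It was 0.86 without the first citronella library and 0.82 without the second. Without the first and the second lemongrass library it was 0.95 and 0.99.

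**Figure D3:**
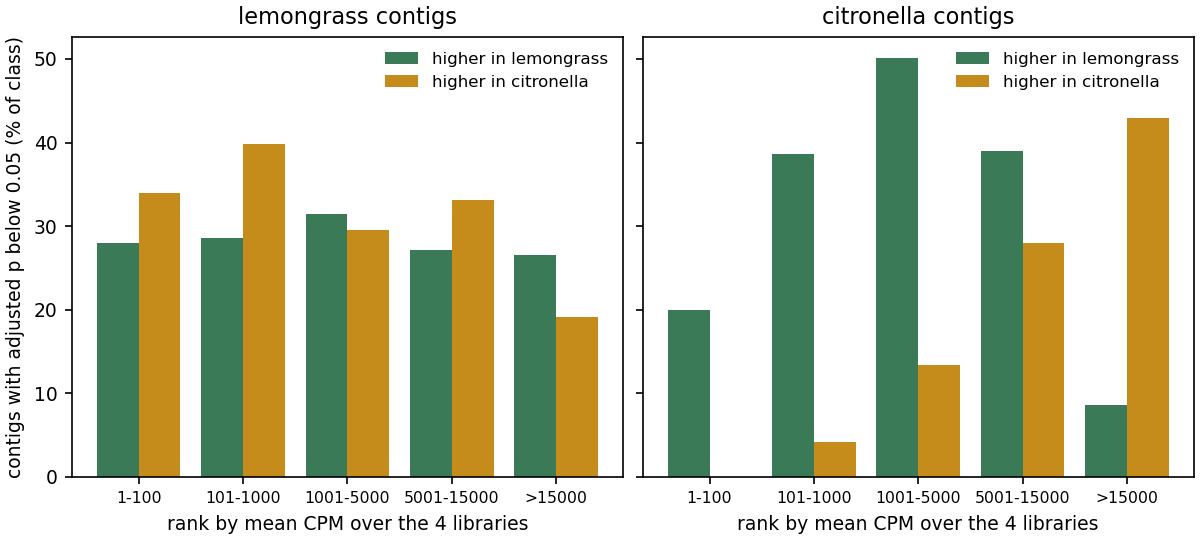
Share of contigs in each abundance class with an adjusted p below 0.05 (y axis, percent of the class), by rank of the mean CPM over the 4 libraries (x axis). Green bars are contigs higher in lemongrass and orange bars contigs higher in citronella. On citronella contigs (right), 20 of the leading 100 are higher in lemongrass and 0 in citronella, and the order turns below rank 15000.

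Of the 4 lemongrass contigs named by the rule, those higher in lemongrass differed most. g.contigcf10874 had 74 and 93 counts in the lemongrass libraries and 0 in both citronella libraries, so it was at least 64.3-fold higher in lemongrass (adjusted p = 7.31e-09 by edgeR). g.contigcf1931 was an abundant contig at 1089 ± 16.8 CPM in lemongrass and 1.91 ± 1.07 CPM in citronella (SD, n = 2). Its log2 fold change was -9.30 ± 0.18 (SE), with an adjusted p of 4.18e-18 by edgeR, and the counts gave a 652-fold difference (95% exact interval 438 to 1018). The log2 fold change was -8.56 without the first citronella library. In the other direction, g.contigcf19389 stood at 43.8 ± 21.3 CPM in citronella against 1.77 ± 1.65 CPM in lemongrass, a log2 fold change of 4.68 ± 0.42 (SE) with an adjusted p of 2.05e-08. That log2 fold change was 6.14 and 3.93 without the first and the second lemongrass library, and 4.06 without the second citronella library. g.contigcf25145 stood at 40.9 ± 4.27 CPM in citronella against 1.57 ± 0.76 CPM, a log2 fold change of 4.67 ± 0.29 (SE) with an adjusted p of 8.23e-11. Its log2 fold change was 5.32 without the second lemongrass library.

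On citronella contigs, the 2 contigs higher in citronella named by the rule had 0 counts in lemongrass. g.contigcw5271 had 695 and 515 counts in the citronella libraries, a mean of 106 ± 8.02 CPM, and was at least 423-fold higher in citronella (adjusted p = 1.78e-10 by edgeR). g.contigcw5972 had 741 and 477 counts and was at least 426-fold higher (adjusted p = 1.57e-10). Higher in lemongrass were g.contigcw38346, at 177 ± 11.6 CPM against 1.84 ± 0.12 CPM in citronella, and g.contigcw35479, at 121 ± 4.82 CPM against 2.32 ± 0.81 CPM. Their log2 fold changes were -7.00 ± 0.26 and -6.10 ± 0.22 (SE), each with an adjusted p of 1.57e-10 by edgeR. No named contig lost its call or changed direction under any alternative in which it was tested. As they were picked for the largest called folds in these libraries, this says little about other contigs. The files do not name the genes behind these contigs.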

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

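For the species comparison, the alternatives with cyclic loess offsets, with a mean count of 50 or more, and for near-absent contigs were chosen after seeing the data. On lemongrass contigs the counts called stayed within 1.5 times under RLE, upper-quartile and no scaling, other filters, DESeq2 (5090 higher in citronella, 5098 lower), limma-voom, cyclic loess offsets and each library left out (5000 to 7002 higher, 5244 to 6794 lower). The test against a 2-fold change called 1765 higher and 2617 lower there, and 7518 higher and 2267 lower on citronella contigs, as a stricter hypothesis must. On citronella contigs, library totals alone left 3544 lower, DESeq2 called 7604 higher and cyclic loess offsets 7174 higher. A mean count of 50 or more tested 14437 citronella contigs and called 4304 higher and 3693 lower. For these alternatives the cause was not tested. Leaving out each library gave 9568 to 11082 higher and 6216 to 9283 lower. Of calls on citronella contigs, 11141 of 19809 were shared with the cyclic loess fit. The replicate block called 6394 higher and 6574 lower on lemongrass contigs, and 10996 higher and 7717 lower on citronella contigs. The numbers share no stated plant or batch, and the deviations of same-numbered libraries correlated at -0.12 and -0.06 across contigs.

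All 127 refits of the 8 named contigs kept direction and call. These contigs were picked as the largest called folds in the same libraries, so this outcome was close to fixed beforehand. Allowing 10 counts in the other species made near-absent contigs 775 (from 183) and 6803 (from 3348) in the contigs' own direction, and 10 and 66 (from 0) in the opposite. Leaving the first library of the species named by the prefix out of both criteria made the opposite 73 and 363 (from 0). Detection at 1 count or more gave 25561.5 lemongrass contigs in lemongrass and 25425.5 in citronella, and 37342 and 41904.5 citronella contigs. Detection at 1 CPM moved the lemongrass means to 25301 and 27624.5 on the 2 sets, and thinning to the smallest library moved them to 24117 and 23027.5. Contigs over 2-fold apart between replicates depended on the pseudocount. On lemongrass contigs they numbered 891 (lemongrass) and 1194 (citronella) at 0.1 CPM, and 0 and 53 at 10 CPM. On citronella contigs they numbered 1381 and 6419 at 0.1 CPM, and 0 and 198 at 10 CPM. With a mean count of 50 or more they fell to 8, 202, 14 and 864 in that order. Without a count filter the lemongrass libraries had 1205 on citronella contigs, and with TMM-scaled CPM the citronella libraries had 2066 there. Of 44 other Pearson correlations and shares, 17 moved past their spread, all correlations. A share from 1 of 2 libraries cannot. The alternatives for gene lists were not run, since no contig is paired with a name. Depth, dispersion and 2 libraries per species limit calls of small differences to an extent not measured here. Simulated 2-fold changes were recovered in 37% and 30% of cases, but with 200 changed contigs per table. The data gave 13754 and 19809 calls against 136 and 97 in the simulations, so the adjustment was less strict in the data.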

Other observations

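The tests in the 3 paragraphs that follow were chosen after the patterns had been seen. Most citronella contigs had at least 1 count in each lemongrass library: of 42250, 5121 and 4695 had 0 counts in the first and second. Lemongrass leaves detected 24814 ± 458 of their own contigs and 24183 ± 851 citronella contigs (10 or more counts, SD, n = 2), although the citronella set is larger.

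In the first citronella library, abundant citronella contigs were low: among 24 contigs with 6400 or more counts in the second library, the median log2 CPM ratio was -1.85. A difference in the RNA of that library is argued against by the same ratio on lemongrass contigs, -0.15 (95% bootstrap interval -0.21 to -0.08, 36 contigs). Reads shared between near-identical citronella contigs would be lost from all libraries counted alike. Among the 100 citronella contigs most abundant in lemongrass, the second library stood at -0.28 (-0.41 to -0.23) against the lemongrass mean and the first at -1.61. The lemongrass libraries were counted on the same contigs, so these ratios cannot show such a loss. They show only that the 2 citronella libraries were not lowered alike. What lowered the abundant contigs in this column stays open. At 100 to 200 counts in the second library, the raw ratio of the first to the second was 1.62 on citronella contigs and 2.06 on lemongrass contigs.

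Large species differences leaned to the species named by the contig prefix: 72.6% (95% Wilson interval 71.0 to 74.2) of calls of 4-fold or more on lemongrass contigs and 87.2% on citronella contigs. A one-sided difference between the species is argued against as the sole cause, since 27.4% of such calls were higher in citronella on lemongrass contigs and 87.2% on citronella contigs. Choice of contigs near the lower count limit of 1 library was examined among contigs with a mean count of 50 or more. With the first library of that species left out of the fit, 55.4% (52.9 to 57.9) and 74.4% still leaned that way. With that library alone left out the shares were 63.1% and 77.7%, and with the count filter alone 60.7% and 78.8%, so both changes lowered the lean. The shares that remained cannot decide the question. The mean ran over all 4 libraries and set no minimum in the contigs' own species. Large folds in the opposite direction still needed low counts there. The choice of contigs stays open beside true differences in expression and the species of the contig set. The last could act through contigs present in 1 species alone or reads that match the other species' contigs less well. These sources could not be separated without sequences.

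Few contigs had low counts in the first library of the species named by their prefix: 16 lemongrass contigs had under 5 counts in the first lemongrass library and 273 in the second, deeper one, which argues against depth. Thinned to the total of the second, the first citronella library had 395 such citronella contigs against 4386. For citronella a difference in the RNA of like size is argued against, as far as lemongrass contigs hold the same transcripts. At equal totals its first library had 48.7% (95% exact interval 46.9 to 50.5) of such cases there, against 8.05% on its own set. For lemongrass the shares were 50.1% (49.5 to 50.7) on citronella contigs and 4.29% on its own set, but this cannot decide. On citronella contigs 13199 and 13137 had under 5 counts in the lemongrass libraries, against 16 and 357 on lemongrass contigs. A like number of contigs would hardly move the share there. A candidate explanation is that contigs were built or kept from the reads of the first library: contig number followed its counts more closely, by 0.0238 in absolute rho (0.0219 to 0.0260) for lemongrass and 0.0379 for citronella at equal totals. The citronella libraries also differed by 0.0301 on lemongrass contigs, so for citronella this measure is not specific.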
